A study of Escherichia coli with 8 samples.

How the data were processed

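RNA from anaerobic cultures of Escherichia coli MG1655 with CORM-3 and from paired cultures without it was hybridised to 8 dual-colour arrays. Per the labels, the arrays make up 4 biological repeats, and each repeat was hybridised with CORM-3 RNA in Cy3 on 1 array and in Cy5 on the other. Per the labels' protocols, about 9 µg of RNA was reverse transcribed with random hexamers and dye-bearing dCTP.

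The deposited values are log2 ratios for each array, as made by the authors and, per the series' protocols, of Cy3 over Cy5. Per the series' protocols, an Affymetrix 428 scanner was used, spots were quantified with local background correction in Imagene 4.0, and spots marked bad, negative or poor were removed before statistics in GeneSight 3.5. Per the same protocols, the mean signals of each channel were log2 transformed and Lowess normalized within each array. The filter that left 281 of 4608 features blank on all 8 arrays, with no feature partly blank, is not given in the sources used here. Single-channel signals were not analysed here, so signal over background, and with it the precision of dim spots, could not be judged. Medians of the deposited log2 ratios lay between -0.0601 and 0.0109 per array, and their SDs between 0.92 and 1.17. The series' protocols name the ratio as Cy3 over Cy5, and the labels name the dye of each culture, and the direction was taken from both. It was not checked against single-channel signals, and if the deposited ratios were Cy5 over Cy3, every sign would turn. The ratios of the 4 arrays with CORM-3 in Cy5 were therefore multiplied by -1, so that each value is CORM-3 over control.

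Gene names came from the platform annotation. Of the 4327 features with values, 4079 had 1 gene symbol, none had several and 248 had none, and these are named by their feature ID. Gene IDs were looked up in a table of the ASM584v2 assembly, where 4086 matched and 1 did not, and 197 symbols were updated. That table served only for names and for which genes neighbour each other. Features of the same gene were averaged, which concerned 47 genes, of which 24 had features of opposite sign, and 4280 genes or unnamed features were tested.

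The arrays of each repeat were averaged after turning, so that n = 4. Genes changed by CORM-3 were tested in R 4.3.3 with limma 3.58.1 (lmFit on an intercept, then eBayes, two-sided), with Benjamini-Hochberg adjustment at 0.05 over all genes and a value required in at least 3 repeats. SDs are plain SDs over the 4 repeats, and intervals are limma's moderated 95% intervals. Fold changes are powers of the mean log2 ratio. The median moderated standard error of a gene was 0.293 on the log2 scale. Dye effects were tested in the same way on the difference between the orientations of each repeat, divided by 2.

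Shifts of 37 gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists. Each list's call is given beside the adjusted p with an estimated correlation, and fry was run as a further alternative. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone. The tests, lists, named genes and most alternatives were chosen before the data were examined. The named genes are the 12 largest increases and 12 largest decreases past the threshold with the same sign in 4 repeats, 17 genes fixed in advance, and up to 4 members with the largest mean change in each list described. The rest of the 39 changed genes and some further genes are named too, after their values had been seen, which makes 109. Of the genes fixed in advance, cpxP was not matched to a feature and is not analysed here.

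Alternatives were all arrays with the repeat as a random block, with and without a dye term, each orientation alone, median centring, scaling and quantile normalization of arrays, rules for missing values, robust and unmoderated tests, a test against 1.5-fold, and leaving out each repeat. Removing the median of each print subgrid was added after the data had been seen, as was leaving spy out of its lists. The gene test was tested on simulated data for the treatment comparison over 4280 genes, where it recovered 21% of genes changed by 1 and 95% of genes changed by 2 on the log2 scale, with 7 false calls among 123. The list test, on 100 simulated draws without any shift, called a list in 2 draws, and it called a TCA cycle list shifted by 0.5 in 20 of 20 draws. The simulated genes were drawn independently of each other. These draws therefore do not show how often the list test errs where the genes of a list are correlated.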

Results

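Growing cells of Escherichia coli MG1655 were exposed without oxygen to CORM-3, a water-soluble ruthenium carbonyl compound that releases carbon monoxide. The cultures used glycerol as carbon source and fumarate as electron acceptor in vessels sparged with nitrogen. CORM-3 was added to 100 µM at an OD600 of 0.4, and RNA was taken after 15 min. Treated and untreated cultures were compared directly on 8 dual-colour arrays, which made up 4 biological repeats, each hybridised in both dye orientations. A log2 ratio was given for 4327 of 4608 features on each array, and the same 281 features were blank on all arrays. After the dye-swapped arrays of each repeat had been averaged, the 6 pairs of repeats correlated across genes with r from 0.112 to 0.206, where genes are not independent replicates. The number of arrays limits the precision of every value below. Each direction rests on the stated form of the ratio, Cy3 over Cy5, and on the dye labels, and was not checked against the single-channel signals.

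The question was which transcripts differ between anaerobic cells with and without CORM-3. The gene for the periplasmic chaperone Spy, spy, rose 112-fold, by 6.80 ± 0.17 on the log2 scale (SD, n = 4, adjusted p = 1.19e-08), the largest change among the genes tested. The copper efflux genes cusC, cusF, cusB and cusA, the zinc uptake genes zinT and znuA, the efflux pump genes mdtA and mdtC and the sulfate uptake genes cysA, cysU and cysW rose by 1.38 to 3.17 on the same scale. The glyoxylate bypass genes aceB and aceA, the aerobic glycerol 3-phosphate dehydrogenase gene glpD, the acid resistance genes gadB and gadC and the formate dehydrogenase O genes fdoG and fdoH fell. In all, 25 of the 4280 genes and unnamed features tested rose and 14 fell (limma, Benjamini-Hochberg adjusted). All 39 changed by at least 2-fold, with the same sign in 4 of 4 repeats. At an unadjusted p under 0.05 there were 183 higher and 217 lower genes.

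Fewer genes passed in each fit leaving out 1 repeat: 27 without repeat 1, 14 without repeat 2, 18 without repeat 3 and 26 without repeat 4. Each such fit also rests on fewer repeats, so a lost call need not mean that 1 repeat carried it. The genes passing were 12 higher and 2 lower without repeat 2, and 13 higher and 5 lower without repeat 3. The genes that passed in each fit leaving out 1 repeat were 12 of the 39, namely spy, zinT, znuA, mdtA, cusF, cusB, cysA, ymgD, mutL, glpD and the unnamed features 3.1.13.12 and 2.1.13.12. Each of the others lost its adjusted call without at least 1 of the repeats, with the sign of its mean kept.

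**Figure D1:**
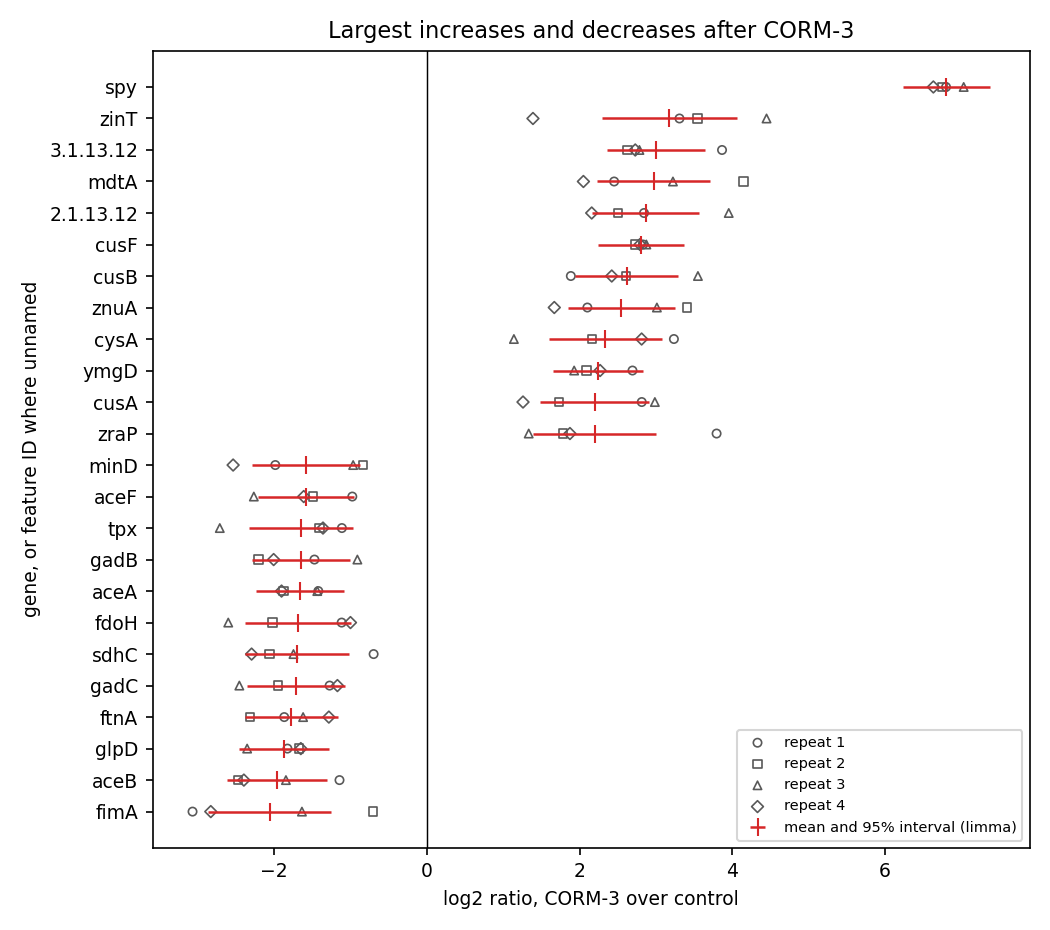
Log2 ratio of CORM-3-treated over control cells (horizontal axis) for the 12 largest increases and 12 largest decreases past the adjusted threshold (vertical axis), with open symbols for the 4 repeats and red bars for the mean and its 95% limma interval. The mean of spy was 6.80, and the means of the other 11 raised genes lay between 2.20 and 3.17.

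Envelope stress genes were among those that rose. The efflux pump genes mdtA (2.97 ± 0.92), mdtC (1.67 ± 0.64) and mdtD (1.39 ± 0.52) rose, all SDs being over 4 repeats. So did the periplasmic protease and chaperone gene degP (1.67 ± 0.60, adjusted p = 0.0185) and the membrane protease gene htpX (1.51 ± 0.52, adjusted p = 0.0239). Of the 8 measured genes of the Bae response and its efflux pumps, 4 rose and 4 did not pass, or 7 rose when adjusted over the list alone. The gene mdtB, for another subunit of the MdtABC pump, stood at 1.33 ± 1.03 and did not pass over all genes (adjusted p = 0.173). The mean log2 ratio of that list was 2.05 ± 0.23 (SD of the list mean over the 4 repeats) and its median 1.36, with a camera adjusted p = 9.04e-15 (adjusted p = 0.126 with an estimated correlation). Of the 11 measured genes of the Cpx envelope stress list, spy, degP and htpX rose, or 5 genes adjusted over the list alone. The Cpx list had a mean of 1.31 ± 0.35, a median of 0.81 and a camera adjusted p = 9.03e-10 (adjusted p = 0.132 with an estimated correlation). Its member yccA stood at 1.32 ± 0.61 and did not pass over all genes (adjusted p = 0.0697). The gene spy belongs to both lists, and without it their means were 1.38 and 0.76. In the sigma E list, degP was the 1 gene of 11 that rose, over all genes and adjusted over the list alone, and the list mean was -0.04 ± 0.18 (adjusted p = 0.666).

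Genes for copper export and genes for zinc uptake were also among those that rose. The 4 structural genes of the Cus system, which exports copper and silver ions from the periplasm, rose by 2.81 ± 0.06 (cusF), 2.62 ± 0.69 (cusB), 2.20 ± 0.84 (cusA) and 1.80 ± 1.08 (cusC). The zinc-responsive periplasmic protein gene zraP rose by 2.20 ± 1.09 (adjusted p = 0.0135). These were the 5 of 15 zinc and copper export genes that rose, or 7 adjusted over the list alone. The mean of the list was 1.03 ± 0.25 and its median 0.42 (camera adjusted p = 2.86e-10, and adjusted p = 0.132 with an estimated correlation). The zinc exporter gene zntA stood at 0.32 ± 0.23 and did not pass (adjusted p = 0.802). Of the 6 zinc uptake genes, zinT, for a periplasmic zinc-binding protein, rose by 3.17 ± 1.29 and znuA, for the binding protein of the high-affinity zinc transporter, by 2.55 ± 0.80. These 2 also passed when adjusted over the list alone, while the other 4 did not, among them znuC (0.41 ± 0.84), ykgM (0.38 ± 0.43) and znuB (0.37 ± 0.32). The zinc uptake list had a mean of 1.14 ± 0.28, a median of 0.40 and a camera adjusted p = 7.38e-05 (adjusted p = 0.132 with an estimated correlation). Among 32 iron uptake genes none passed, over all genes or adjusted over the list alone, and the list mean was 0.10 ± 0.11 (adjusted p = 0.34), with the enterobactin receptor gene fepA at 0.61 ± 0.72.

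Some sulfur assimilation genes rose. The sulfate and thiosulfate transporter genes cysA (2.34 ± 0.91), cysU (1.59 ± 0.56) and cysW (1.38 ± 0.18) rose, as did cysH (2.02 ± 0.74), for phosphoadenosine phosphosulfate reductase. They were the 4 of 24 cysteine and sulfur assimilation genes that passed over all genes, and 13 rose adjusted over the list alone, with 19 of 24 means above 0. The list mean was 0.76 ± 0.28 and its median 0.70 (camera adjusted p = 9.30e-11, and adjusted p = 0.132 with an estimated correlation). The binding protein gene cysP was measured at 1.45 ± 0.81 (adjusted p = 0.0656). The methionine biosynthesis list stood at 0.07 ± 0.10 (adjusted p = 0.639), with metF at 0.33 ± 0.67.

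The heat shock list passed with a mean of 0.46 ± 0.32 over 17 genes (camera adjusted p = 9.93e-05, and adjusted p = 0.333 with an estimated correlation). None of its genes passed over all genes tested, and 4 rose adjusted over the list alone: the heat shock sigma factor gene rpoH (1.26 ± 1.12), the chaperonin genes groS (1.06 ± 0.26) and groL (0.94 ± 0.29) and the disaggregase gene clpB (0.97 ± 0.64). The small heat shock gene ibpB had a mean of -0.09 ± 0.70. On the arrays with CORM-3 in Cy3 alone the list mean was 0.30 and no longer passed (adjusted p = 0.132).

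Other raised genes belonged to none of the lists. The mismatch repair gene mutL rose by 1.80 ± 0.19 (adjusted p = 0.00518). The adjacent genes ymgD (2.25 ± 0.33) and ymgG (2.05 ± 0.80) rose, as did ybjG (1.60 ± 0.46), the diguanylate cyclase gene dgcZ (1.46 ± 0.63) and ybjX (1.41 ± 0.53). A pair of features without a gene symbol, 3.1.13.12 (3.00 ± 0.58) and 2.1.13.12 (2.86 ± 0.78), rose by more than most named genes. As read from the form of their IDs, these features were printed at the same position of different subgrids. Whether they measure neighbouring genes is not known.

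Genes of central carbon and energy metabolism were among those lowered. The glyoxylate bypass genes aceB, for malate synthase, and aceA, for isocitrate lyase, fell by 1.96 ± 0.61 and 1.66 ± 0.27 on the log2 scale (adjusted p = 0.00671 and 0.00898). The gene of the aerobic glycerol 3-phosphate dehydrogenase, glpD, fell by 1.87 ± 0.33 (adjusted p = 0.00518). The pyruvate dehydrogenase subunit gene aceF fell by 1.58 ± 0.53, and the succinate dehydrogenase subunit gene sdhC fell by 1.70 ± 0.70. Of 15 TCA cycle genes, sdhC alone passed over all genes and 3 fell when adjusted over the list alone, with 14 of 15 means below 0. The mean of the TCA list was -0.64 ± 0.29 (camera adjusted p = 2.22e-07, and adjusted p = 0.178 with an estimated correlation), and its member gltA, for citrate synthase, stood at -1.23 ± 0.37 (adjusted p = 0.0656). All 13 NADH dehydrogenase I genes had means below 0, from nuoA at -1.08 ± 0.70, and none passed over all genes or adjusted over the list alone. That list had a mean of -0.60 ± 0.30 (camera adjusted p = 1.34e-06, and adjusted p = 0.309 with an estimated correlation).

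The formate dehydrogenase O genes fdoH and fdoG fell by 1.68 ± 0.76 and 1.56 ± 0.76, the 2 of 35 hydrogenase and formate dehydrogenase genes to pass, or 3 adjusted over the list alone. The mean of that list was -0.36 ± 0.20 (camera adjusted p = 7.69e-05, and adjusted p = 0.303 with an estimated correlation). Of 13 glycerol and glycerol-3-phosphate genes, glpD passed over all genes and 3 adjusted over the list alone. The glycerol list had a mean of -0.46 ± 0.37 and a median of -0.14 (camera adjusted p = 0.00476, and adjusted p = 0.346 with an estimated correlation), with glpK at -1.14 ± 0.94 and glpA, for the anaerobic dehydrogenase, at -0.14 ± 0.18. No cytochrome oxidase gene of 11 passed over all genes and 2 fell adjusted over the list alone, the terminal oxidase genes cydA (-1.45 ± 0.75) and cyoB (-1.09 ± 0.46). The means of 8 of the 11 lay below 0, while cyoE (0.66 ± 0.84), cyoC (0.28 ± 0.60) and cyoD (0.14 ± 0.55), of the same operon as cyoB, stood above it. The oxidase list had a mean of -0.31 ± 0.19 (camera adjusted p = 0.0415, and adjusted p = 0.346 with an estimated correlation), and cyoA stood at -0.43 ± 0.26. On the arrays with CORM-3 in Cy5 alone, the lists of the TCA cycle (-0.19), glycerol (-0.20), hydrogenases (-0.20) and oxidases (-0.23) no longer passed. Without repeat 3 the glycerol list (-0.30) no longer passed, nor did the oxidase list without repeat 2 (-0.33), without repeat 4 (-0.22) or with CORM-3 in Cy3 alone (-0.40). With all 8 arrays, a dye term and the repeat as a random block, the oxidase list (-0.31) did not pass either (adjusted p = 0.0555).

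Some acid resistance genes fell. The glutamate-dependent acid resistance genes gadC and gadB fell by 1.71 ± 0.60 and 1.65 ± 0.58, and hdeD fell by 1.47 ± 0.59. These were 3 of 12 acid resistance genes, or 4 adjusted over the list alone. The mean of that list was -0.61 ± 0.07 and its median -0.39 (camera adjusted p = 2.00e-05, and adjusted p = 0.132 with an estimated correlation), and it did not pass on the arrays with CORM-3 in Cy3 alone (-0.44). A feature for gadB may also bind the transcript of its near-identical copy gadA. In the RpoS general stress list none of 13 genes passed over all genes and 5 fell adjusted over the list alone, among them wrbA (-1.47 ± 0.91) and elaB (-1.28 ± 1.15), with 11 of 13 means below 0. Its mean was -0.57 ± 0.25 (camera adjusted p = 9.93e-05, and adjusted p = 0.178 with an estimated correlation). Outside the lists, the fimbrial subunit gene fimA fell by 2.06 ± 1.10, the ferritin gene ftnA by 1.77 ± 0.44, the thiol peroxidase gene tpx by 1.65 ± 0.72 and the cell division gene minD by 1.58 ± 0.82.

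The other 3 lists that passed held no gene past the threshold over all genes tested. The iron-sulfur cluster assembly list had a mean of -0.36 ± 0.29 over 13 genes, with sufD at -0.83 ± 0.38, and none passed adjusted over the list alone (camera adjusted p = 0.00734, and adjusted p = 0.309 with an estimated correlation). The tryptophan and aromatic biosynthesis list had a mean of -0.31 ± 0.18 and a median of -0.18 over 18 genes (camera adjusted p = 0.0107, and adjusted p = 0.309 with an estimated correlation). Adjusted over the list alone, its genes trpD (-1.39 ± 0.85) and trpE (-1.31 ± 0.84) fell. The 54 ribosomal protein genes had a mean of -0.15 ± 0.26, below 0 in 3 of 4 repeats (camera adjusted p = 0.0407, and adjusted p = 0.514 with an estimated correlation), with none past either adjustment and rplU at -0.88 ± 0.54. On the arrays with CORM-3 in Cy5 alone none of the 3 lists passed (-0.11, -0.07 and -0.19), nor did ribosomal proteins with CORM-3 in Cy3 alone (-0.11). Leaving out repeat 1 ended the call of iron-sulfur assembly (-0.23), repeat 3 that of tryptophan (-0.25), and repeats 2 and 3 that of ribosomal proteins (-0.15 and -0.04), which print subgrid centring ended too (-0.13, adjusted p = 0.107).

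**Figure D2:**
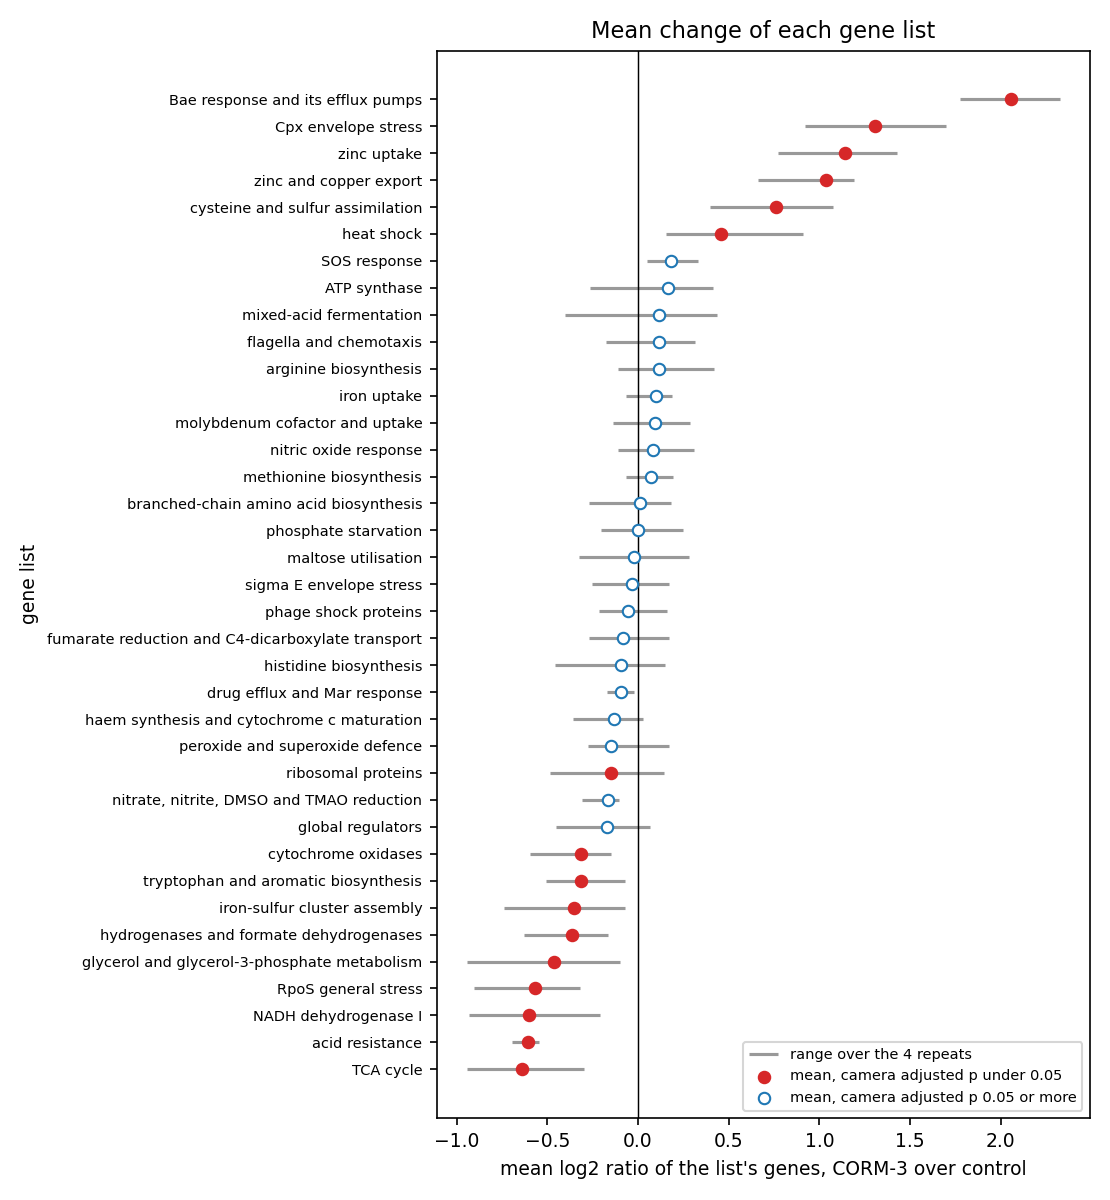
Mean log2 ratio of CORM-3-treated over control cells for each of the 37 gene lists (horizontal axis; lists on the vertical axis), with grey bars for the range of the list mean over the 4 repeats and filled red points for lists past the camera adjusted threshold. Means ran from -0.64 for the TCA cycle to 2.05 for the Bae response, and no list passed with an estimated correlation.

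The other 21 lists did not pass the test, with means from -0.17 to 0.18 and adjusted p from 0.0758 to 0.973. The fumarate reduction and C4-dicarboxylate transport list, the route of respiration in this medium, stood at -0.08 ± 0.18 (adjusted p = 0.639) and its gene frdA at -0.20 ± 0.63. The nitrate, nitrite, DMSO and TMAO list stood at -0.17 ± 0.09 (adjusted p = 0.2), with narG at -0.29 ± 0.65. The nitric oxide response list had a mean of 0.08 ± 0.18 (adjusted p = 0.639) and the flavohaemoglobin gene hmp was at 0.05 ± 0.59. The SOS list had a mean of 0.18 ± 0.12 (adjusted p = 0.0758), with recA at 0.36 ± 0.25. The peroxide and superoxide list was at -0.15 ± 0.21 (adjusted p = 0.311), with the catalase gene katG at -0.87 ± 0.46 (adjusted p = 0.312). The arginine list was at 0.11 ± 0.22 (adjusted p = 0.432), with argC at -0.07 ± 0.31. None of the genes in these 6 lists passed over all genes or adjusted over the list alone.

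Across the 37 lists, 6 rose and 10 fell with camera's preset correlation, and none passed with an estimated correlation, where 8 had an unadjusted p under 0.05. The estimate was below 0 for the Bae response (-0.080), zinc uptake (-0.049) and acid resistance (-0.028), and above 0 for the other called lists. Correlation between genes therefore does not account for the loss of those 3 calls. How far it accounts for the loss of the other calls was not tested. By fry, which asks only whether a list's genes move on balance in one direction, 5 lists passed: the Bae response, Cpx envelope stress, zinc and copper export, zinc uptake and acid resistance. The other 11 of the 16 lists lost their call by fry, with adjusted p from 0.0606 for sulfur assimilation to 0.476 for ribosomal proteins.

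With all 4 repeats, more genes passed for the dye orientation than for the treatment, an effect that averaging each swapped pair cancels. The difference between the orientations, divided by 2, differed from 0 for 91 genes, 58 brighter in Cy3 and 33 brighter in Cy5 (limma, adjusted). The phosphoglycerate dehydrogenase gene serA (3.10 ± 1.02, SD, n = 4) and the phosphoglucosamine mutase gene glmM (3.38 ± 1.40) led the Cy3 side and were singled out after their values had been seen. Their treatment ratios, -0.31 for serA and 0.10 for glmM, did not pass. None of the 39 genes changed by CORM-3 was among the 91, and 859 genes had an unadjusted p under 0.05 for the dye. Arrays of the same orientation correlated across genes with a median r of 0.233 after turning, and the 4 swapped pairs with a median r of -0.0548. The order of the counts turned without repeat 1, with 5 dye genes against 27 for the treatment, and without repeat 3, with 15 against 18. Without repeat 4 there were 30 dye genes against 26.

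**Figure D3:**
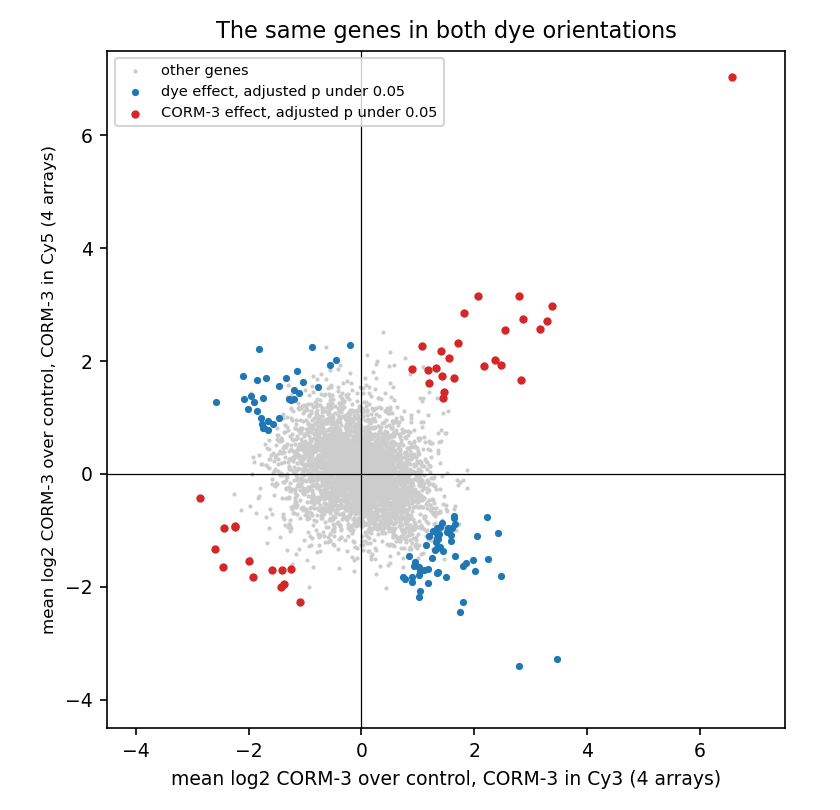
Mean log2 ratio of CORM-3-treated over control cells on the 4 arrays with CORM-3 in Cy3 (horizontal axis) and on the 4 arrays with CORM-3 in Cy5 (vertical axis), each point a gene or unnamed feature. The 39 genes changed by CORM-3 (red) lie in the quadrants of equal sign and the 91 dye genes (blue) in those of opposite sign.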

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

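Some tests here were chosen after the result had been seen: that of the dye orientations, the count of sign patterns for genes, the removal of print subgrid medians, the comparisons of neighbouring genes, and the zinc test.

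Single repeats stood far from the other 3 in 7 of 109 named genes and 3 of 37 lists, where chance alone marks about 1 group in 20. The unnamed feature 3.1.13.12 was at 3.86 in repeat 1, against 2.63 to 2.78 in the others. In repeat 1, recA was at -0.018 against 0.48 to 0.49, gltA was at -0.67 against -1.47 to -1.34, and arcA was at -0.47 against -1.22 to -1.20. In repeat 3, cyoA was at -0.82 against -0.33 to -0.28, and in repeat 4, rplU was at -1.69 against -0.65 to -0.59 and mgtA at 0.55 against 1.10 to 1.21. The mean of the zinc and copper export list was 0.66 in repeat 4 against 1.10 to 1.19. The nitrate, nitrite, DMSO and TMAO list was at -0.31 in repeat 3 against -0.13 to -0.11. The peroxide and superoxide list was at 0.17 in repeat 2 against -0.27 to -0.24. The dye orientations differed in serA and glmM, with a difference divided by 2 of 3.10 and 3.38 (limma, adjusted p = 0.00129 and 0.00171).

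The 39 changed genes were weighed against artefacts of dye and printing. A dye effect that averaging had left behind would give opposite signs in the 2 orientations. All 39 kept their sign, and 35 of 39 reached an unadjusted p under 0.05 in both. They were picked on the mean of both orientations, which favours this outcome, so it cannot exclude such an effect. After the median of each of 16 print subgrids had been removed, 37 of 39 still passed, which argues against a subgrid trend. With the signs of the repeats turned in each of the 8 possible patterns, the real pattern gave 39 genes and the highest other 0, and for lists 16 and 9, and for dye genes 91 and 0. In each of these, 1 of 8 patterns was as large as the real one, and 8 patterns are too few for a share under 0.05.

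Changed genes often lay side by side on the chromosome. Of 37 changed genes with a place in the gene order, 17 were next to another, against a mean of 0.564 and at most 7 in 1000 random sets. All 10 such pairs, among them cusC and cusF or aceB and aceA, were also printed at the same position of different subgrids, as read from the form of the feature IDs, as were 2542 neighbouring pairs over all genes, against 993 at different positions, so print position could add to the pattern. Symbols starting with y were left out of the comparison by letters, which held 672 same-position pairs with shared letters and 760 without. Neighbours at the same position correlated in their treatment ratios with r = 0.542 (95% bootstrap interval 0.451 to 0.62) if their symbols shared the first 3 letters. If not, r was 0.107 (0.0499 to 0.177), so a shared position alone went with a weaker correlation. The changed pairs share these letters, so those compared, which leaves out ymgD and ymgG, may themselves have raised the first value. The comparison therefore cannot exclude position as the whole cause for those pairs. A part played by position stays open: neighbours that shared letters but not the position correlated less, with r = 0.256 (0.0861 to 0.397), and in the dye difference the same-position values were 0.265 with shared letters and 0.275 without. The 27 same-position pairs that are not neighbours gave r = -0.102 (-0.462 to 0.285), too few to decide.

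Some copper export and zinc uptake genes rose in the same cells. Excess zinc stays open: of the genes that respond to it outside the pattern, zraP rose (2.20 ± 1.09, SD over 4 repeats) while zntA was at 0.32 ± 0.23 with an upper 95% bound of 0.89, and the rise of zinT and znuA, which goes against it, is what picked the pattern out. A general excess of copper would raise copA and cueO, the copper exporter and oxidase genes of the cytoplasmic copper sensor's regulon, but the higher of their upper 95% bounds was 0.64 (though cueO was at 0.87 with CORM-3 in Cy5 alone), against a mean rise of 2.36 for cusC, cusF, cusB and cusA. What in the CORM-3 exposure raised both groups was not tested.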

How the results depend on the processing

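The count of 39 changed genes stayed within 1.5 times (27 to 49) in all alternatives run except those that follow, but on the arrays with CORM-3 in Cy5 alone 15 of the 27 genes were shared with the 39. It fell to 15 with CORM-3 in Cy3 alone (11 shared) and to 10, all higher, against a 1.5-fold change. Without moderation it fell to 3 (2 shared), where 3 residual degrees of freedom set each gene's spread. It was 73 at an unadjusted p under 0.05 with 2-fold. Leaving out single repeats gave 14 to 27 genes (14 without repeat 2, 18 without repeat 3) and 13 to 16 lists. The 16 lists fell to 9 on the arrays with CORM-3 in Cy5 alone, to 5 by fry and to 0 with an estimated correlation. The dye count of 91 was 5 to 131 without single repeats (5, 15 and 30 without repeats 1, 3 and 4), and 87 after median centring. The causes of these changes were not tested, and some of these fits used fewer arrays. The rules for missing values removed no gene. Subgrid centring, added after the data had been seen, gave 40 genes (37 shared) and 15 lists, without ribosomal proteins. What low signal limits could not be judged, as single-channel signals were not analysed.

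Alternatives were computed gene by gene for the 109 named genes, of which 22 changed the sign of their mean in at least 1. None of the 22 had passed over all genes, but glpX had passed adjusted over its list alone. With CORM-3 in Cy5 alone these were zntA (-0.029), narG (0.18), hmp (-0.088), ibpB (0.18), metF (-0.14), argC (0.71), glpX (0.0024), sdhD (0.21), ykgM (-0.059), rpsK (0.13), copA (-0.27), cueO (0.87), znuB (-0.088) and glmM (-3.28), and with CORM-3 in Cy3 alone glpA (0.15), recA (-0.20), znuC (-0.18), aceE (-0.81), cyoC (-0.24), cyoD (-0.37) and serA (2.80). After subgrid centring hmp was at -0.035, copA at -0.097 and glmM at -0.034. After scaling cueO was at 0.029 and glmM at -0.075, and after quantile normalization cueO was at 0.056. Without single repeats the means ran from -0.46 to 0.028 for frdA, -0.23 to 0.24 for hmp, -0.28 to 0.21 for ibpB, -0.21 to 0.030 for argC, -0.092 to 0.22 for copA, -0.19 to 0.15 for cueO, -0.095 to 0.31 for cyoD and -0.62 to 0.49 for glmM.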

Other observations

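The groups in this part were written down after the data had been seen, and the tests of the wider ArcA and PhoP sets were each fixed before their own result was computed, except the lower bound for the ArcA set and the PhoP genes outside the operons already seen, which were chosen after it. Of 7 genes of the glyoxylate bypass and the pyruvate dehydrogenase complex, 3 fell over all genes (aceB, aceA and aceF), and the other 4 did not pass, with lpd, the shared lipoamide dehydrogenase gene, at -1.74 ± 1.09 (SD, n = 4, adjusted p = 0.0518). The group mean was -1.06 ± 0.31, while aceE, for another subunit of the same complex, was at 0.23 ± 0.38. Of 7 type 1 fimbriae genes, fimA fell and the others did not pass, with a group mean of -0.72 ± 0.45.

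Some genes controlled by the magnesium-responsive regulator PhoP had high means besides ybjX. The regulator gene phoP was at 1.50 ± 1.22, mgrB at 1.34 ± 1.56, rstB at 1.19 ± 0.86 and the magnesium transporter gene mgtA at 1.01 ± 0.31, and none of these passed over all genes. Of 10 measured members ybjX alone rose over all genes. A candidate explanation is a response of the wider PhoP regulon. The 5 members whose values had not been looked at had a mean of 0.58 ± 0.28, above 0 in 4 of 4 repeats (unadjusted camera p = 0.00131 as a list test and p = 0.0697 with an estimated correlation, neither exact). Among them phoQ shares an operon with phoP and rstA with rstB. Without these, the remaining 3 had a mean of 0.59 ± 0.35, above 0 in 4 of 4 repeats (unadjusted camera p = 0.00986 and p = 0.111 with an estimated correlation, neither exact). A set of 11 genes around the related regulator BasR had a mean of 0.08 ± 0.30. Besides lipopolysaccharide modification genes, that set holds basR, basS and pmrD.

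The lower means of the TCA cycle and NADH dehydrogenase lists could reflect stronger repression by ArcA, the regulator that represses aerobic metabolism. Both lists lost their call with an estimated correlation and by fry. A set of 19 other ArcA-repressed genes, for fatty acid, lactate, glycolate and betaine oxidation, had a mean of 0.10 ± 0.25, above 0 in 2 of 4 repeats, with a lower 95% bound of -0.29. The set holds none of the lowered genes aceB, aceA and glpD, so its mean does not speak for them. For these genes, that bound excludes a mean fall as large as that of the TCA list (-0.64) but not a smaller one. Single-channel signals were not analysed, so whether these genes were expressed enough to fall further could not be judged. The explanation therefore cannot be told apart from others. The gene arcA itself was at -1.03 ± 0.37 and did not pass over all genes (adjusted p = 0.155), but was the 1 of 13 global regulator genes that fell adjusted over the list alone.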
